A study of Homo sapiens with 15 samples.

How the data were processed

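RNA from 5 tumours was measured on 15 one-colour Affymetrix oligonucleotide arrays. Each tumour, taken to be a numbered set of the labels, gave 1 array after treatment with IPI-504 and 2 arrays without treatment. There were thus 5 treated and 10 untreated arrays. IPI-504 (retaspimycin hydrochloride) is a hydroquinone form of 17-AAG and inhibits the chaperone HSP90. The series title places the work in pancreatic cancer. The labels used here give neither the dose nor the time of treatment, and they do not say whether the tumours were grown as xenografts. Total RNA was extracted with Trizol, and 6 ug of it was turned into biotin-labelled cRNA, per the labels' protocols.

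The deposited table held 1 linear signal intensity per probe set and array, for 54675 probe sets. The intensities were made with MAS5, per the submitters' processing notes, with no version stated. MAS5 reduces the probe pairs of a probe set to 1 signal and scales each array to a target mean. The trimmed mean of each deposited column (2% left out at each end) was 150 on all 5 treated arrays and on both untreated arrays of set 2, and 100 on the 8 untreated arrays of sets 1, 3, 4 and 5. The columns were therefore not in a common unit. Every array was rescaled here to a target of 100 before any test. The design fixed before the data were examined had planned no further scaling, and the signals as deposited were kept as an alternative. A factor per array changes no ranking of genes within an array. It moves the deposited treated minus untreated log2 difference by 0.58 in 4 of the 5 sets. The number of arrays limits the precision of all values.

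A pseudocount of 1 was added and log2 taken, which understates changes of the lowest signals but does not remove their variation between arrays. Probe sets whose mean lay above the median of all means were kept. Of the probe sets, 41091 were annotated with 1 gene symbol in the platform annotation, 1801 with several, 11721 with none, and 62 were controls. Probe sets with 1 symbol stood for 19752 genes; 43 probe sets received a newer symbol from the RefSeq gene table of assembly GRCh38.p14, which was used for names alone. A gene was represented by its probe set of highest mean. A set of 95 probe sets of sex-linked genes was left out. No gene was named from a probe set annotated with several genes, and those of HSPA1A and HSPA1B are given by probe set.

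The main comparison averaged the untreated duplicates of each set and fitted treated against untreated with the set as a block (10 values, 5 pairs) in limma 3.58.1 under R 4.3.3, with eBayes and an intensity trend. Tests were two-sided and p-values were adjusted by Benjamini-Hochberg at a threshold of 0.05. The pairing comes from the set numbers in the labels, and each set was taken as 1 of the 5 tumours of the series design. Treated arrays correlated with the untreated arrays of their own set at a mean r of 0.769 across probe sets where the 2 arrays lay on different scales, against 0.652 for untreated arrays of another set on a different scale. With the untreated arrays of set 2, on their own scale, the treated arrays of sets 1, 3 and 5 correlated more (0.792, 0.848 and 0.815) than with those of their own set (0.739, 0.726 and 0.789), and that of set 4 less (0.769 against 0.821). Nothing says that the 2 untreated arrays of a set are separate pieces of tumour, so they counted once, and duplicate spread may be technical.

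Gene lists, 34 in all (pathways around HSP90 inhibition and pancreatic carcinoma, and markers of cell types a tumour sample can hold), were written before the data were examined. The 30 with at least 5 measured genes were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. Islet cells, endothelium, blood and adipocytes had 2, 2, 3 and 2 measured genes and were not tested. Within a set there is 1 treated array and no test; list medians of set 2 were placed among 10000 random lists of the same size matched on mean expression. In the outer 5% of these lay 9 of 30 lists for the 2 untreated arrays of set 2 and 10 for its change on treatment, so an extreme percentile does not set a list apart from array variation. The difference of response between sets and the difference between untreated tumours were F-tests in limma, over 15 and 10 arrays, whose spread comes from the untreated duplicates. A fit with a term for the 2 target scales was added after seeing the data.

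Genes were named by a rule fixed beforehand. It took the HSP90 and HSF1 genes, and the 12 largest rises and 12 largest falls among genes past the threshold with 1 sign in all 5 sets. It also took up to 4 members of each list past the threshold by p (or the 2 of smallest p where none passed), the 10 genes of widest range between tumours, and up to 8 of widest range of response. Other genes are said to have been chosen after their values were seen. On data simulated for the paired comparison over 13050 genes, 30% of genes changed by 1 log2 unit were recovered, 92% at 2 and 100% at 3, with 11 false calls. Genes shifted by array batch alone, by 4 log2 units, were called in 100% of cases without the batch term. With it they were called in 5% (15 arrays) or 0% (10 values). Changes of 4 on treatment were recovered in 100% too, so the 100% followed from the size chosen. Smaller batch shifts were not simulated. How often a change on treatment is recovered with the batch term was not simulated. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

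The alternatives tried were the fit without the set block, all 15 arrays in place of averages, the set as a random block, 1 untreated array alone, another pseudocount, other filters, quantile normalization, centring on the median, no trend, array weights, an unmoderated paired statistic, the median of a gene's probe sets, other thresholds, and leaving out each set. Added after seeing the data were the signals as deposited, 2 fits with a batch term, and set 1 without its untreated array 1.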

Results

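The study asked which genes differ in expression between tumours treated with the HSP90 inhibitor IPI-504 and untreated ones. Signals were read from 15 arrays of 5 tumours, numbered as sets 1 to 5, with 1 treated and 2 untreated arrays per tumour. Values below are on the log2 scale, treated minus the mean of the untreated pair. The standard error (SE) after ± is the moderated one of the limma fit of 5 pairs unless stated. It draws on the spread of other genes, so it is not the SE of the 5 changes alone. After rescaling, the median signal of an array ran from 18.6 to 49.0. Untreated duplicates correlated with a mean Pearson r of 0.894 across probe sets (0.833 to 0.954). In set 1, the 3′ to 5′ signal ratio of GAPDH, a sign of RNA degradation when high, was 14.2 and 4.32 on the untreated arrays and 2.60 on the treated one. The other 12 arrays lay between 1.04 and 1.82.

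The arrays fell into 2 technical groups that overlapped almost fully with treatment. The 5 treated arrays and both untreated arrays of set 2 had been scaled by the submitters to a mean of 150, and the 8 untreated arrays of sets 1, 3, 4 and 5 to 100. Bacterial and phage transcripts added as hybridisation controls separated the same arrays after rescaling, with no overlap in 15 of 18 control probe sets. The probe set AFFX-r2-Ec-bioD-5_at, for example, had a median signal of 3987 in the 7 arrays and 3.15 in the 8. After rescaling, the median over all probe sets was 33.2 to 49.0 in the 7 arrays and 18.6 to 36.8 in the 8. Signals below 16 made up 25.0 to 33.5% and 33.1 to 46.7% of an array. A single factor per array thus left the spread of signals unlike between the groups. Changes across the groups can therefore vary with signal level. Set 2 was the only tumour whose treated and untreated arrays lay in 1 group, so its values are given beside the medians of gene lists and those of several genes.

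On the probe set used for each gene, HSP90 and its regulators showed no change that passed the test. HSP90AA1, the stress-inducible cytosolic HSP90, differed by 0.11 ± 0.26 (adjusted p = 0.805), and HSP90AB1, the constitutive form, by -0.16 ± 0.27 (adjusted p = 0.709). The endoplasmic reticulum form HSP90B1 differed by 0.79 ± 0.32 (adjusted p = 0.125), or 0.39 without set 1, where it differed by 2.39, and the mitochondrial form TRAP1 by -0.31 ± 0.24 (adjusted p = 0.400). HSF1, the transcription factor of the heat shock response, differed by -0.30 ± 0.29 (adjusted p = 0.502), and the HSP40 gene DNAJB1 by -0.09 ± 0.35 (adjusted p = 0.887). These are limma p-values. In set 2 the 6 genes differed by -0.10, -0.04, -0.02, 0.08, 0.59 and 0.27 in the same order. Of 8 further probe sets of these genes, 2 passed as separate features, 211969_at of HSP90AA1 at 2.99 ± 0.64 (adjusted p = 0.0301) and 216450_x_at of HSP90B1 at 3.36 ± 0.58 (adjusted p = 0.0278), with -0.056 and 0.065 in set 2. The other 2 of HSP90AA1 differed by 0.35 and 0.91. With the signals as deposited, HSP90AB1, TRAP1, HSF1 and DNAJB1 took the opposite sign, at 0.31, 0.16, 0.16 and 0.38. Quantile normalization turned HSP90AB1 (0.39) and DNAJB1 (0.18), and centring on the median turned HSP90AA1 (-0.35).

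HSP70 induction is the usual sign of HSP90 inhibition, and HSPA1A and HSPA1B share their probe sets on this array. Probe set 202581_at, annotated to both, was higher on the treated array in all 5 sets, by 3.79, 0.34, 0.88, 3.06 and 2.75 (mean 2.17 ± 0.45, adjusted p = 0.0288 over probe sets by limma). In set 2 the treated signal was 604 against 497 and 456 untreated. The changes of sets 1, 3, 4 and 5 compare arrays across the 2 array groups. Untreated signals were 132 and 252 in set 1, 58.4 and 121 in set 4, and 90.3 and 79.9 in set 5. These lay below untreated set 2, which had no drug and shares the group of the treated arrays. In set 3 they were 467 and 531. The treated signals of sets 1, 3, 4 and 5 were 2537, 920, 709 and 578, above both untreated arrays of set 2 in the same group. That comparison is between different tumours, whose untreated levels in this group were not measured. The rise can therefore not be told apart from a difference between array groups. Probe set 200799_at, annotated to the same 2 genes, differed by 0.02 ± 0.26 (adjusted p = 0.959), with a change of 1.02 in set 1 and -0.62 in set 3. The third, 200800_s_at, also annotated to HSPA1L, differed by 0.67 ± 0.38 (adjusted p = 0.254).

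**Figure D1:**
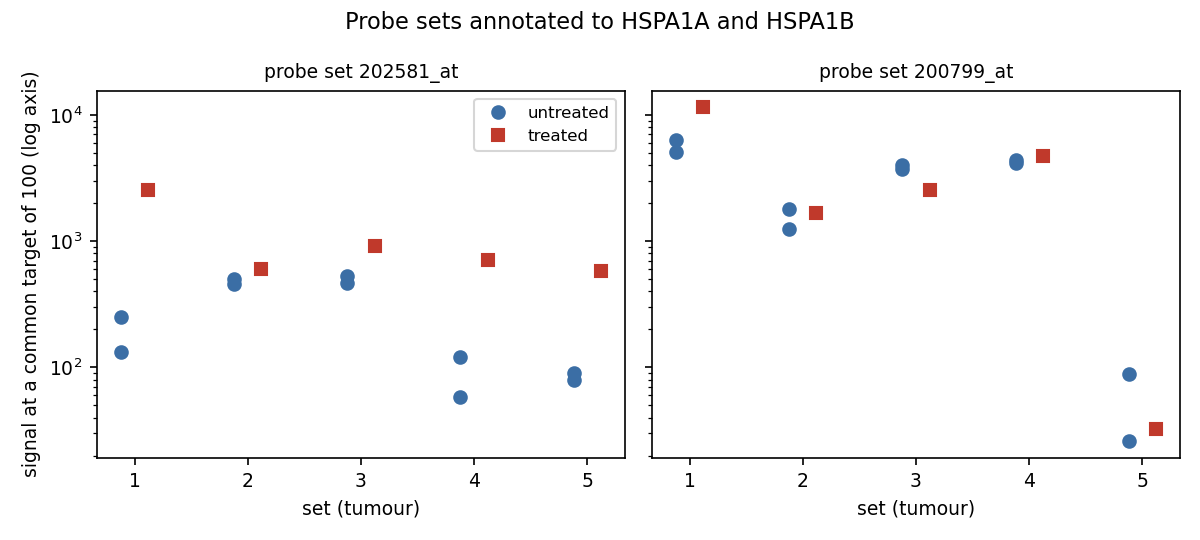
Signal of the 2 probe sets annotated to HSPA1A and HSPA1B on each array, rescaled to a common target of 100, on a log axis against the set (tumour) number; circles are the untreated arrays and squares the treated one. For 202581_at the treated array lies above both untreated arrays in all 5 sets, and for 200799_at it does so in sets 1 and 4.

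Among genes past the threshold with 1 sign in all 5 sets, the largest rises on treated arrays were in ASXL2, ZNF292 and ZNF91, and the largest falls in P2RY2, DMAP1 and TOMM40L. ASXL2, a Polycomb-associated chromatin gene, was higher by 3.65 ± 0.49 (12.5-fold, adjusted p = 0.0185), and the zinc finger genes ZNF292 and ZNF91 by 3.56 ± 0.46 and 3.36 ± 0.42 (both adjusted p = 0.0185). The histone gene H3-3A was higher by 3.07 ± 0.53, the lysosomal membrane gene TMEM192 by 3.05 ± 0.60, the mitochondrially encoded ND6 by 3.04 ± 0.47 and SOD2, the mitochondrial superoxide dismutase, by 2.97 ± 0.52. NOTCH2NLA, SET, CLUHP3, SATB1 and RSF1 were higher by 2.91, 2.89, 2.86, 2.78 and 2.78. Other probe sets of ASXL2, ZNF292, ZNF91 and RSF1 differed by as little as 0.13, 1.19, 0.68 and 0.71. Among the falls were P2RY2, a nucleotide receptor (-2.54 ± 0.52, adjusted p = 0.0276), DMAP1 (-2.51 ± 0.54), TOMM40L (-2.42 ± 0.54), the extracellular matrix gene ECM1 (-2.38 ± 0.35, adjusted p = 0.0185) and the cytidine deaminase CDA (-2.36 ± 0.52). CDK5, PHKG2, BMP4, DUOX2, RPTOR, CDCA8 and ZFYVE28 were lower by values from -2.35 to -2.10. Mean treated signals were low for P2RY2 (10.4), DMAP1 (10.6), TOMM40L (9.62), CDK5 (14.4), RPTOR (12.4) and ZFYVE28 (12.6), against 215 for ECM1 and 224 for DUOX2. PHKG2, CDA and BMP4 had treated signals of 24.4, 25.0 and 25.0. Among the rises, mean untreated signals were low for CLUHP3 (14.4), TMEM192 (16.8), SATB1 (26.8), ZNF91 (28.2) and H3-3A (29.1), against 114 for ASXL2 and 529 for SET. Between the set 2 duplicates DMAP1, CDK5 and RPTOR differed by -2.14, -2.16 and 2.24, more than on treatment there (-1.10, -0.86 and -0.84). P2RY2, TOMM40L and ZFYVE28 differed by -0.22, -0.22 and 0.28 between these duplicates. Genes past the threshold without 1 sign in all sets included larger rises, in MALAT1 (5.38), MAP3K2 (4.06) and TNPO1 (3.86, chosen after its values were seen), and the fall in SPRR3 (-2.48).

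In all, 760 of 13050 genes passed the threshold in the paired limma fit, 317 higher and 443 lower. Of the 760, 577 had 1 sign in all 5 sets, as had 20.7% of all genes tested. The paired test itself favours genes of 1 sign. With the signals as deposited the count was 2799, of which 2655 were higher, and with arrays centred on their median it was 2887, of which 229 were higher. These scalings moved the median change of all genes from 0.03 to 0.49 and to -0.43. With the filter at the 75th percentile of mean signal 795 genes passed, 235 higher and 560 lower, and the median change was -0.13. Leaving out sets 1 to 5 in turn gave 18, 2400, 0, 0 and 9 genes in limma, with 2517 and 2779 at an unadjusted p under 0.05 without sets 3 and 4. Without the set block (10 values) or without the intensity trend 0 genes passed, with 1748 and 3768 unadjusted, and the paired block over 15 arrays gave 1868. As separate features, 2199 of 27259 probe sets passed, 1618 higher and 581 lower. A second probe set opposed the one used for ZFYVE28, PSMD11, BIRC5, RFC5, PHLDA1, TPI1, KRT7, DUSP4, MT1F, CCT5, ERO1A, TNNT3, IGHM, HSP90AB1, DNAJC1 and NNMT, and for DUSP4 it passed the threshold in the other direction at 2.66.

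In set 2 the 12 genes of largest rise among those of 1 sign differed by less than in any other set, and some of the largest falls were of similar size there. The 13 rises as large without 1 sign in all sets were all falls in set 2. ASXL2, ZNF292, H3-3A, ND6 and SET differed there by 0.48, 0.64, 0.00, 0.15 and 0.14, against 4.31, 3.83, 3.28, 4.22 and 3.66 in set 1. P2RY2, CDA, ZFYVE28, DUOX2, BMP4 and ECM1 differed in set 2 by -2.95, -3.42, -2.63, -2.15, -2.02 and -1.83. Over the 760 genes, the median size of the change was 1.47 in the other sets and 0.37 in set 2, where the duplicates differed by 0.25. With a batch term in the limma fit, whose treatment effect rests on set 2, 0 genes passed with 10 values (208 at an unadjusted p under 0.05). With 15 arrays 3 passed (283 unadjusted), of which 0 were among the 760. They were PDGFC, ZBED2 and IGF2BP3, chosen after their values were seen. In set 2 PDGFC, a platelet-derived growth factor, differed by 4.90.

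Changes of sets 1, 3, 4 and 5 resembled each other and not those of set 2. Across genes, which are not independent replicates, the Pearson r between the changes of 2 of these sets was 0.38 to 0.60, and that of set 2 with each was -0.06, 0.12, 0.01 and -0.05. Genes called from sets 1, 3, 4 and 5 alone and measured in the full comparison numbered 2382, and 1141 of them (47.9%) had the same sign in set 2.

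**Figure D2:**
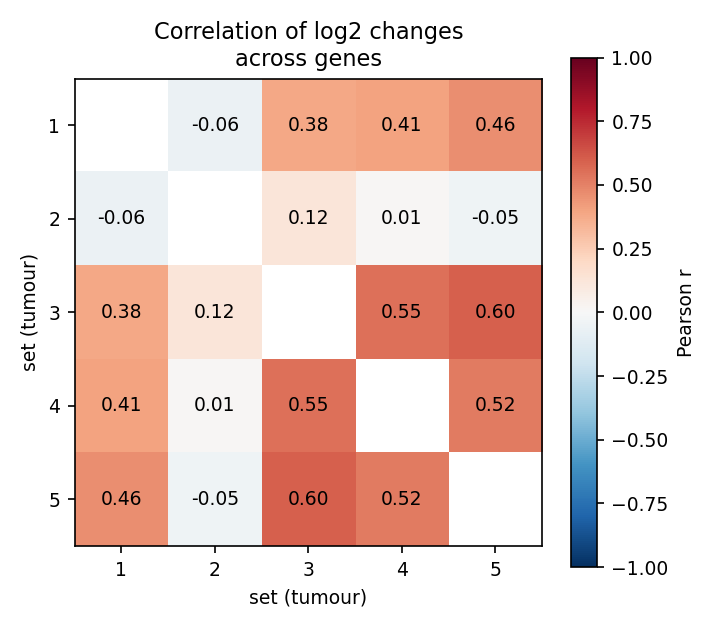
Pearson r, across 13050 genes, between the log2 changes (treated minus untreated) of each 2 sets, with the set number on both axes and colour from -1 to 1. Pairs among sets 1, 3, 4 and 5 lie between 0.38 and 0.60, and pairs with set 2 between -0.06 and 0.12.

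Of the 30 gene lists, 11 were lower on treated arrays by camera and 0 higher. Cell division genes were among them: 4 of 33 mitosis genes fell (11 adjusted over the list alone), namely CDC20 (-1.49 ± 0.31), the kinase PLK1 (-1.45 ± 0.31), the survivin gene BIRC5 (-1.51 ± 0.34) and UBE2C (-0.94 ± 0.25), and the list's median was -0.52 (adjusted p = 8.86e-06). In set 2 the median was 0.12, and in sets 1, 3, 4 and 5 it was -0.84, 0.037, -0.98 and -1.08. The untreated duplicates of set 1 differed by 0.87. Of 19 glycolytic genes 3 fell (13 adjusted over the list alone), TPI1 by 1.26, ALDOC by 1.42 and PFKP by 1.06, with a median of -0.88 (adjusted p = 8.86e-06) and of 0.14 in set 2. With an estimated correlation 0 of the lists passed, each of the 11 at adjusted p = 0.756, and with fry 0 passed (lowest adjusted p = 0.269).

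MAPK feedback and immediate early genes were lower too. Of 16 genes of MAPK feedback, the outputs of ERK signalling, 4 fell (9 adjusted over the list alone): PHLDA1 (-1.11 ± 0.25), EPHA2 (-1.07 ± 0.26), DUSP4 (-0.93 ± 0.24) and MYC (-1.16 ± 0.31). The list's median was -0.75 (adjusted p = 0.000275) and 0.19 in set 2, where MYC differed by 0.42. Of 16 immediate early genes CCN1 (-1.35 ± 0.28) and KLF4 (-1.42 ± 0.32) fell (4 adjusted over the list alone), with a median of -0.56 (adjusted p = 0.000636) and 0.26 in set 2 (-0.86 with set 2 left out). With an estimated correlation both lists had adjusted p = 0.756.

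Ribosomal, respiratory chain, proteasome and NRF2 genes were also lower. Of 29 ribosomal protein genes 1 fell (0 adjusted over the list alone), RPS15 (-1.09 ± 0.29), and the median was -0.51 (adjusted p = 8.86e-06). Quantile normalization turned that median to 0.10, and in set 2 it was 0.29. Of 25 respiratory chain genes UQCRC1 (-1.32 ± 0.27) and COX4I1 (-1.07 ± 0.26) fell (4 adjusted over the list alone), with a median of -0.57 (adjusted p = 4.35e-05) and 0.20 in set 2. Of 27 proteasome genes 6 fell and 1 rose (11 and 1 adjusted over the list alone), with PSMB7, PSMD8 and PSMC4 at -1.15, -1.53 and -1.11, PSMD11 at 1.25, and a median of -0.43 (adjusted p = 0.000322). In set 2 the proteasome median was -0.12. Of 18 NRF2 target genes TALDO1 fell by 1.13 (5 adjusted over the list alone), with a median of -0.35 (adjusted p = 0.00867) and 0.07 in set 2. Leaving out set 3 moved the NRF2 median to -0.22 (adjusted p = 0.0316), and leaving out set 4 to -0.14, no longer past the threshold (adjusted p = 0.124). For these lists adjusted p = 0.756 with an estimated correlation. In set 1 the ribosomal, respiratory chain, proteasome and NRF2 medians changed by -0.50, -0.48, -0.28 and -0.21. Between the untreated duplicates of set 1 they differed by more, at 0.68, 0.90, 1.07 and 0.68.

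Interferon, sterol and epithelial lists were lower in set 2 as well. Of 19 interferon response genes 7 fell (8 adjusted over the list alone), among them OASL (-1.69 ± 0.31), ISG15 (-1.34 ± 0.28), MX1 (-1.44 ± 0.32) and OAS1 (-1.28 ± 0.30). Their median was -0.35 (adjusted p = 0.00867) and -0.45 in set 2, where 16 of the 19 lay below both duplicates. In set 5 the interferon median was 0.13. Leaving out sets 1 to 5 in turn gave -0.68, -0.30, -0.22, -0.099 and -0.63, with adjusted p = 0.0707 without set 2 and 0.105 without set 4. Of 16 cholesterol synthesis genes FDPS fell by 1.43 (2 adjusted over the list alone), with a median of -0.61 (adjusted p = 0.000885) and -0.52 in set 2, with 13 below both duplicates. The cholesterol synthesis median was 0.10 in set 4. Of 24 genes of ductal and carcinoma epithelium LCN2 (-1.72 ± 0.26), KRT7 (-1.45 ± 0.31), KRT19 (-1.16 ± 0.27) and KRT18 (-0.94 ± 0.25) fell (9 lower and 2 higher adjusted over the list alone), with a median of -0.38 (adjusted p = 0.00697) and -0.21 in set 2, where the duplicates differed by -0.27. With an estimated correlation adjusted p = 0.756 for all 3. As deposited, the medians of interferon, ductal, proteasome and NRF2 genes were 0.10, 0.09, 0.04 and 0.12.

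**Figure D3:**
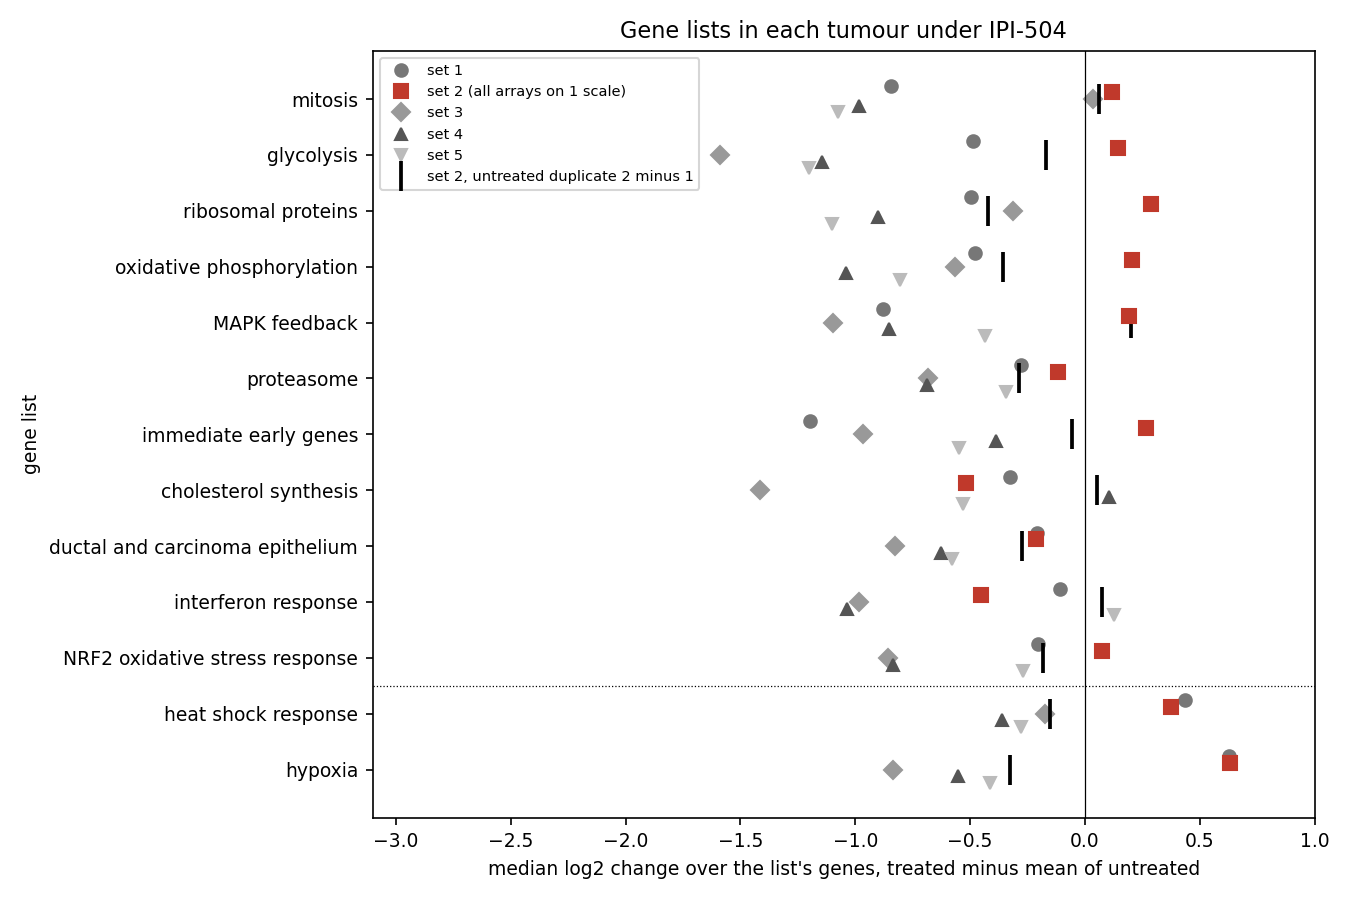
Median log2 change (treated minus the mean of the untreated arrays) over the genes of the 11 lists called by camera and, under the dotted line, 2 lists not called, for each set; bars are the median difference between the untreated duplicates of set 2. The squares of set 2 lie right of 0 for 7 of the 11 lists and left of it for proteasome, cholesterol synthesis, epithelium and interferon response.

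The remaining 19 lists did not pass. The heat shock response had 0 of 21 genes past the threshold and a median of -0.04 (adjusted p = 0.893), with HSPH1 at 0.74 ± 0.23 (adjusted p = 0.0654) and DEDD2 at -0.84 ± 0.31. Its median in set 2 was 0.37. HSP90 co-chaperones had a median of -0.10 with STUB1, a chaperone-linked ubiquitin ligase, lower by 0.99. Medians were -0.07 for genes of HSP90 clients, where BIRC5 fell, and -0.34 for DNA replication, where RFC5 differed by 1.12 and MCM5 by -0.93. NF-kB cytokines had a median of -0.05, with LCN2 and CXCL1 at -1.72 and -1.91 and SOD2 at 2.97. p53 targets had -0.41, with TP53INP1 at 1.03. The unfolded protein response had -0.27 (SEL1L 0.82, CRELD2 -0.77), metallothioneins 0.01 (MT1G 0.86, MT1F -0.76), the cytosolic chaperonin -0.21 (CCT7 -0.66, CCT5 -0.43) and apoptosis regulators -0.13 (XIAP 0.92, BIK -0.76). Hypoxia had -0.19 (ERO1A -0.69, P4HA1 0.64), angiogenic factors -0.41 (HBEGF -0.61, ANGPT1 0.98) and the mesenchymal transition -0.23 (ZEB2 0.64, TGFBI -0.87). Leaving out a set made 4 of these lists pass. They were metallothioneins without set 4 (0.90, adjusted p = 0.00178), the unfolded protein response without set 1 (-0.47, adjusted p = 0.0144), DNA replication without set 2 (-0.45, adjusted p = 0.0372) or 3 (-0.30, adjusted p = 0.0319) and squamous epithelium without set 5 (-1.05, adjusted p = 0.00474). Medians in set 2 were -0.15 for co-chaperones, -0.025 for clients, 0.28 for DNA replication, -0.00066 for NF-kB cytokines and 0.18 for p53 targets. They were -0.059 for the unfolded protein response, 0.19 for metallothioneins, 0.16 for the chaperonin, -0.097 for apoptosis regulators, 0.63 for hypoxia, -0.18 for angiogenic factors and -0.18 for the mesenchymal transition.

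Of the tested cell type lists, only ductal and carcinoma epithelium passed. The squamous list had a median of -0.45 with SPRR3 lower by 2.48, acinar cells 0.30 with PRSS2 lower 2.83-fold, and macrophages 0.45 with AIF1 higher by 1.43. Fibroblast markers had -0.04 (COL3A1 -0.71, COL5A2 0.41), muscle 0.02 (TNNT3 -1.28, MYL9 -1.28) and lymphocytes -0.11 (TRBC1 -0.95, IGHM -1.37); none of these 6 genes passed. Medians of these 6 lists in set 2 were -1.36, -0.67, 0.066, -0.52, -0.082 and -0.39 in this order. The two-sided exact sign-flip permutation test over the 5 sets could not go below p = 0.0625, and 0 lists passed it after adjustment.

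The change differed between sets for 7 genes by the limma F-test (1123 at an unadjusted p under 0.05). Each set had 1 treated array, the spread was that between untreated duplicates, which may be technical, and a contrast of set 2 with the others was also one of array groups, so these values do not show a difference of response to the drug. MALAT1, a nuclear non-coding RNA, differed by 4.77, 8.92, 7.38 and 6.94 in sets 1, 3, 4 and 5 and by -1.13 in set 2 (adjusted p = 0.0385). The kinase MAP3K2 showed 3.58, 5.53, 4.87 and 6.54 against -0.21 (adjusted p = 0.0102), and DNAJC1 5.04, 3.67, 3.64 and 3.69 against -0.38 (adjusted p = 0.0385). Other probe sets of MALAT1, MAP3K2, DNAJC1 and KLK10 had mean changes of 1.19, 0.18, -0.18 and -0.055 at the far end from these. KLK10 differed by 2.20 in set 2 and by -1.94, -3.55, -4.50 and -1.21 elsewhere. PKIB stood out in set 4 (-5.62), PDGFC in set 2 (4.90) and TM4SF4 in set 1 (1.79) and set 2 (-2.76). Without set 2, 0 genes passed (618 unadjusted), without set 4 there was 1 and without set 1 there were 27.

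On untreated arrays the tumours differed in 7087 of 13050 genes by the limma F-test. Among sets 1, 3, 4 and 5, which share an array group, 5028 of 13219 genes differed. Set 4 had the highest levels of SPP1, the osteopontin gene (14.3, against 1.79 to 6.81 in the other sets), of the neutrophil chemokine CXCL6 (13.3), of NNMT (12.6) and of the carboxylesterase CES1 (13.4). Set 5 had the highest REG1A, a pancreatic acinar gene (14.1, others at most 3.94), and FABP1, a fatty acid binding protein (13.2), and the lowest CXCL5 (3.07, others at least 10.3). OLFM4 ran from 3.20 in set 1 to 14.4 in set 5, PIGR, the immunoglobulin transporter of mucosal epithelium, from 4.07 in set 1 to 14.1 in set 5, and MUC16, the CA125 antigen, from 1.55 in set 2 to 11.7 in set 1. The spread here is that between duplicate arrays.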

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

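The share of lists moving alike in set 2 and the comparison of heat shock genes with random lists were chosen only after the results had been seen. The fits with a batch term were also added after the data were seen. Of 126 groups of 5 or 10 values examined for a sample far from the others, 22 held one, where chance gives about 1 in 20.

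The treated minus untreated changes of sets 1, 3, 4 and 5 make up the first pattern. An array group effect predicts that the change in 2 of these sets resembles untreated set 2 minus the untreated arrays of the other 2, a difference without drug or shared arrays, and the mean r across genes over the 6 ways of choosing was 0.462 (0.390 to 0.521). A response to IPI-504 shared by all 5 tumours would also appear in set 2, and the r of its change with the mean change of the others was 0.0153, which argues against such a response as the main source, although set 2 has only 1 treated array. The 2 target scales were removed before this change was measured, so the count of genes on the common scale, 0.272 of that as deposited, decided nothing about it. An effect of the drug limited to the other 4 tumours stays open, as the array groups coincide with treatment there.

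Relabelling 1 array of each set as treated gave as many genes as the real labels in 2 of 100 labellings, the real one included. The 100 were the real one, the 2 that differ from it in set 2 alone, and 97 drawn at random from the others of 243. The real value was 760 and the highest other 1165. That other labelling differed from the real one in set 2 alone, so it kept the array groups of the other sets, and the second such labelling gave 340. The highest of the 97 labellings not of this kind was 7. For the main fit, 2 of 100 argues only against a split of the arrays unrelated to drug and array group alike. The 97 others all mixed the array groups within at least 1 set, so the counts cannot tell the drug from the array groups. A fit with a batch term cannot tell them apart either, as its treatment effect rests on the 1 treated array of set 2.

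The lower gene lists are the second pattern. Across lists, the mean r between the changes of 2 sets and the drug-free difference was 0.130 over the 6 ways (-0.152 to 0.339), so the array group as their source cannot be told apart from other sources with so few lists. A response to the drug would move the called lists the same way in set 2, and the share that did was 0.364. Among the 11, the set 2 median exceeded its duplicate difference in size only for 4 lists. They were mitosis (0.12 against 0.061), immediate early genes (0.26 against -0.055), cholesterol synthesis (-0.52 against 0.053) and interferon (-0.45 against 0.076). With 1 treated array in set 2, the share does not decide whether all 5 tumours responded. Interferon, cholesterol synthesis, proteasome and ductal epithelium were the 4 that were lower in set 2 too.

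The higher heat shock genes of set 2 (median 0.37) are the third pattern. The duplicate difference was 0.411 of the change in size, but the duplicates of sets 1 and 5 differed by 0.71 and 0.45, more than that change, so array error stays open. The list lay at percentile 99.96 of random lists, but between the 2 untreated arrays of set 2, with no drug, 9 of 30 lists lay in the outer 5% of random lists (10 on treatment), so chance stays open too. A response shared by the other tumours would put their treated arrays above untreated set 2, as was seen in 4 of the 4 sets (1.46, 0.71, 1.10 and 0.59), but their untreated arrays also lay above it (0.99, 0.68, 0.93 and 1.01), so this test decided nothing. Whether the drug induced these genes in set 2 stays open with 1 treated array.

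Several genes had 1 set far from the other 4. Set 2 stood apart for ASXL2 (0.48), ZNF292 (0.64), SET (0.14), CCT5 (0.16), CDC20 (0.032), PHLDA1 (-0.16), MYC (0.42), UQCRC1 (-0.055), COX4I1 (-0.016) and RPS15 (0.15). Set 3 stood apart for BMP4 (-4.81), P4HA1 (-0.48) and HSP90AA1 (1.13), and set 4 for MT1F (-4.80) and KLF4 (-3.15). Among list medians, NF-kB cytokines in set 4 (-1.11) and lymphocytes in set 1 (0.77) lay apart.

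In set 1, the GAPDH 3′ to 5′ ratio (14.2) and the actin ratio (27.8) of untreated array 1 lay far above those of the other untreated arrays. The treated array of set 1 lay above the other treated arrays in GAPDH ratio (2.60), actin ratio (4.23) and median signal (49.0).

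The change differed between the 5 sets in 7 genes by the F-test. The mean change of sets 1, 3, 4 and 5 differed from that of set 2, a contrast of array groups as well, in 9 genes with 10 values and in 21 with 15 arrays. Hybridisation controls, which no comparison used, separated the 7 arrays scaled to 150 from the 8 scaled to 100. The median signal was 3987 in the 7 and 3.15 in the 8 for AFFX-r2-Ec-bioD-5_at, 1101 and 1.30 for AFFX-BioDn-5_at, and 9462 and 327 for AFFX-CreX-3_at.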

How the results depend on the processing

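The signals as deposited, the batch terms and set 1 without its untreated array 1 were chosen after seeing the data. The cause of the shifts below was not tested. Detection calls were not used here, so how far signals lay above background is known only through the filter on mean signal.

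Genes past the threshold numbered 760 and probe sets 2199. Without the set pairing (no replicate block) there were 0 genes and 0 probe sets with 10 values and with 15 arrays; with the replicate block over 15 arrays there were 1868 and 4837, and with a random block 1564 and 4486. Untreated array 1 alone gave 0 and 404, array 2 alone 238 and 667. No trend and no moderation gave 0 and 0, array weights 3151 and 8255, median centring 2887 and 4273, and the signals as deposited 2799 and 6655. The median of probe sets gave 1201 genes, of which 755 were higher, against 317 of the 760 in the main fit. The balance of rises and falls thus depended on the probe set chosen for a gene. Quantile normalization gave 1374 probe sets and the stricter filter 1270. At threshold 0.10 there were 2338 and 5369, at 0.01 0 and 0. A batch term gave 0 and 0 with 10 values, 3 and 3 with 15 arrays. Leaving out a set gave 0 to 2400 genes (18, 2400, 0, 0 and 9 without sets 1 to 5) and 0 to 6445 probe sets.

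The 11 lists fell to 0 with an estimated correlation and with fry, and 7 of them stayed with quantile normalization, 6 lower and ribosomal proteins higher. Either batch term, with which the change rests on the 1 treated array of set 2 and the spread on the other sets, called 7 lists, 3 higher and 4 lower, of which 3 were among the 11 (cholesterol synthesis and interferon lower, ribosomal proteins higher). Other settings gave 9 to 12. Response differing between sets (7 genes) became 63 with pseudocount 32, 3 without a filter, 13 with the stricter filter, 20 with quantile normalization, 2 with median centring, 0 without a trend and 0 with the median of probe sets, and 0 to 27 leaving out a set. Lists of 1 sign in all 5 sets (3) became 7 with median centring. Genes differing between tumours (5028 to 7970) and the heat shock median of set 2 (0.26 to 0.47) kept their side.

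With either batch term, signs turned for ALDOC (0.21), BIRC5 (0.044), CCT5 (0.16), CCT7 (0.015), CDC20 (0.032), COL5A2 (-0.75), DEDD2 (0.37), DNAJB1 (0.27), ERO1A (0.25), HSF1 (0.59), HSP90AA1 (-0.097), HSP90B1 (-0.017), IGHM (0.93), MYC (0.42), MYL9 (0.67), PFKP (0.30), PSMD11 (-0.074), PSMD8 (0.13), RFC5 (-0.30), RPS15 (0.15), SEL1L (-0.080), TALDO1 (0.12), TRAP1 (0.076), UBE2C (0.035), XIAP (-0.19) and ZEB2 (-0.14), and for the lists MAPK feedback (0.19), NRF2 (0.072), glycolysis (0.14), heat shock (0.37), hypoxia (0.63), immediate early (0.26), mitosis (0.12), oxidative phosphorylation (0.20) and ribosomal proteins (0.29). Array 1 alone turned HSP90AB1 (0.091) and DNAJB1 (0.00287), array 2 alone HSP90AA1 (-0.053). Quantile normalization turned HSP90AB1 (0.39), DNAJB1 (0.18) and ribosomal proteins (0.10), median centring COL5A2 (-0.039) and HSP90AA1 (-0.35), array weights HSP90AA1 (-0.10) and the median of probe sets RFC5 (-0.27). As deposited, CCT5 (0.035), HSP90AB1 (0.31), TRAP1 (0.16), HSF1 (0.16) and DNAJB1 (0.38) turned. Leaving out 1 set in turn gave ranges across 0 for ZFYVE28 (-2.12 to 0.29) and IGHM (-1.94 to 0.54). They lay above 0 for ZFYVE28 without set 1 or 3 and for IGHM without set 3 or 4, where another probe set stood for the gene. Ranges also crossed 0 for MT1F (-1.08 to 0.25, above without set 4) and HSP90AB1 (-0.41 to 0.055, above without set 4). The same held for HSP90AA1 (-0.15 to 0.20, below without set 3) and DNAJB1 (-0.52 to 0.27, above without set 3 or 5).

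Medians of lists turned sign in further settings, called or not. As deposited these were heat shock (0.42), co-chaperones (0.36), unfolded protein response (0.20), NRF2 (0.12), proteasome (0.036), chaperonin (0.26), HSP90 clients (0.40), DNA replication (0.13), p53 targets (0.060), apoptosis regulators (0.33), hypoxia (0.27), interferon (0.10), NF-kB cytokines (0.41), angiogenic factors (0.057), mesenchymal transition (0.23), ductal epithelium (0.086), squamous epithelium (0.012), fibroblasts (0.43) and lymphocytes (0.35). With either batch term they were also chaperonin (0.16), DNA replication (0.28), p53 targets (0.18), acinar cells (-0.67) and muscle (-0.082). Quantile normalization turned heat shock (0.21), unfolded protein response (0.013), chaperonin (0.099), HSP90 clients (0.18), acinar cells (-0.054) and muscle (-0.42), and median centring metallothioneins (-0.44), acinar cells (-0.16), muscle (-0.44) and macrophages (-0.00083). Untreated array 1 alone turned heat shock (0.17), co-chaperones (0.037), HSP90 clients (0.16), interferon (0.085) and fibroblasts (0.032), array 2 alone apoptosis regulators (0.013) and lymphocytes (0.070), and set 1 with array 2 only metallothioneins (-0.17) and muscle (-0.14). Array weights turned metallothioneins (-0.20), fibroblasts (0.00058), muscle (-0.0031) and lymphocytes (0.0049), pseudocount 32 acinar cells (-0.17) and muscle (-0.36), no filter HSP90 clients (0.15), acinar cells (-0.062), fibroblasts (0.011), muscle (-0.41) and lymphocytes (0.32), and the median of probe sets co-chaperones (0.19), HSP90 clients (0.17), p53 targets (0.042) and apoptosis regulators (0.095). Leaving out 1 set in turn gave medians across 0 for heat shock (-0.21 to 0.047, above without set 2, 4 or 5), co-chaperones (-0.15 to 0.023, above without set 5), metallothioneins (-0.31 to 0.90, below without set 2, 3 or 5), HSP90 clients (-0.13 to 0.073, above without set 4), apoptosis regulators (-0.19 to 0.084, above without set 1), hypoxia (-0.47 to 0.061, above without set 3), NF-kB cytokines (-0.45 to 0.084, above without set 4), acinar cells (-0.034 to 0.26, below without set 4), fibroblasts (-0.28 to 0.30, above without set 2 or 4), muscle (-0.21 to 0.032, below without set 1, 2, 4 or 5) and lymphocytes (-0.82 to 0.54, above without set 2, 3 or 4); acinar cells had no value without set 5. Calls of 2 of the 11 lists ended, NRF2 without set 4 (-0.14) and interferon without set 2 (-0.30) or set 4 (-0.099). Other lists that passed on leaving out a set were DNA replication without set 2 (-0.45) or 3 (-0.30), metallothioneins without set 4 (0.90), squamous epithelium without set 5 (-1.05) and the unfolded protein response without set 1 (-0.47).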

Other observations

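In set 2, the tumour with all arrays in 1 group, several gene lists had medians away from 0 on treatment. Of 30 lists, 10 lay in the outer 5% of random lists on treatment and 9 between the untreated duplicates. The medians below are therefore not set apart from array variation, and other sets often had the opposite sign. Genes in this paragraph were chosen after their values were seen, and the difference between the untreated duplicates of set 2 follows each change in brackets. Hypoxia genes had a median of 0.63 (-0.33), with 12 of 16 above both duplicates, and 0.63 in set 1, -0.84 in set 3, -0.55 in set 4 and -0.41 in set 5, which compare arrays across the groups. ADM, a vasodilator peptide gene, differed by 1.58 (-1.33), DDIT4 by 1.34 (-0.23) and NDRG1 by 1.30 (-1.29), so part of this list varied as much without the drug. Heat shock genes had a median of 0.37 (-0.15), and 0.44, -0.17, -0.36 and -0.28 in sets 1, 3, 4 and 5. DNAJB4 differed by 1.88 (-0.31), HSPA4L by 1.31 (0.97), HSPH1 by 1.16 (-0.084) and DNAJB6 by 0.98 (1.20), while CRYAB (-0.73, duplicates 0.80) and HSPB8 (-0.38, duplicates -0.61) went the other way. Cholesterol synthesis genes had a median of -0.52 (0.053), and -0.33, -1.42, 0.10 and -0.53 in sets 1, 3, 4 and 5. In set 2 INSIG1 differed by -1.61 (0.026), HMGCS1 by -1.23 (0.095) and IDI1 by -0.94 (-0.22), while TM7SF2 differed by 0.69 (0.62). Ribosomal protein genes had 0.29 (-0.42), and -0.50, -0.31, -0.90 and -1.10 in sets 1, 3, 4 and 5. All 5 squamous genes lay below both duplicates in set 2, with a median of -1.36 (0.34) and DSG3 at -1.76 (0.0018). The squamous median was -1.17, 0.29, -0.41 and 0.34 in sets 1, 3, 4 and 5.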
